A study of Mus musculus with 2 samples.

How the data were processed

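RNA of uterine stromal cells from pregnant mice, taken on day 5 and pooled over 3 animals for each genotype, was measured on 2 one-colour Affymetrix Mouse Genome 430A 2.0 arrays. Per the labels' protocols, total RNA was extracted with Trizol, cleaned with an RNeasy kit, and amplified and biotin-labelled with the Affymetrix 3' Express kit. A kit of this type starts copying at the poly-A tail. The deposited values are intensities on a linear scale, 1 MAS5 signal per probe set, and per the submitters' processing notes they were made with MAS5 in Affymetrix Expression Console version 1. The target value of the scaling is not given in the sources used here. The values themselves have a mean of 150.1 on each array after 2% of probe sets is trimmed from either end, so the authors' scaling was kept. Detection calls were not used here, and a MAS5 signal near the floor can be noise.

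Samples were grouped from their titles, which name a floxed control and a conditional knockout. The titles, the genotype field and the breeding note name different target genes, so the array is called knockout-labelled throughout. With 1 array per group there is no replicate, no test and no p-value. Lists, rules and alternatives were fixed before the data were examined, except where the text says otherwise.

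Probe sets were named through the platform annotation, with symbols brought up to date through Entrez gene identifiers in a RefSeq gene table of the assembly GRCm38.p6, which gave a symbol for 20351 probe sets. Of 22626 probe sets that are not controls, 20380 have 1 gene symbol, 691 have several and 1555 have none here, and only those with 1 symbol were used, for 12393 genes. Signals were raised to a floor at the 40th percentile of both arrays pooled, a signal of 19.7, and then put on a log2 scale. The log2 ratio is knockout-labelled minus control. A gene with several probe sets took the one with the highest mean log2 signal, and further probe sets of a named gene are given where they went the other way. Genes at the floor on both arrays, 3800 in number, were left out, which left 8593, of which 7866 were above the floor on both. A gene at the floor on 1 array has a bound, written as at least so many fold. The probe set of Gapdh that has 1 symbol was at the floor on both arrays although its control probe sets were bright, so a probe set at the floor is no proof that a gene is silent.

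Genes were counted by a size rule of at least 2-fold. The named genes are Epas1, Hif1a and Rac1, then the 10 highest and 10 lowest log2 ratios among genes above the floor on both arrays whose further measured probe sets had the same sign, then the 3 highest and 3 lowest bounds, and up to 4 members of each list with the largest log2 ratio past 2-fold, or the 2 brightest where none reached it. Transcripts without an established name were counted and not named. There were 24 gene lists. The 14 functional lists covered HIF pathway components, glycolysis and lactate, other hypoxia-responsive genes, decidualization and progesterone response, cell cycle, extracellular matrix, angiogenic factors, vesicle trafficking, prostaglandin, chemokine and inflammatory genes, interferon response, dissociation and immediate-early response, oxidative phosphorylation, unfolded protein response and autophagy, and ribosomal proteins. The 10 marker lists covered uterine stroma, epithelium and glands, endothelium, myeloid cells, granulocytes and mast cells, lymphocytes and NK cells, smooth muscle and pericytes, mesothelium, erythrocytes, and embryo and trophoblast. Some genes stand in more than 1 list, and stroma shares genes with the matrix and decidualization lists. The median log2 ratio of each list with at least 3 members was placed among the medians of 10000 random lists of the same size, matched over 20 bins of mean signal. The matching did not take in the number of probe sets of a gene. Such a percentile describes these 2 arrays and is not a test of the genotype.

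The error of a log2 ratio was estimated from the difference between the 2 brightest probe sets of a gene, over 2660 genes with both above the floor on both arrays. It covers the probe sets and these 2 arrays, and leaves out the spread between animals, pools, labelling reactions and arrays. Control probe sets, 64 in number, entered no gene result and gave the 3' to 5' ratios.

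Alternatives were quantile normalization, centring each array on its median, removal of a loess trend of ratio on signal with a span of 0.4, a floor at the 25th or 60th percentile, a pseudocount of 4.70 (the 20th percentile) with no floor, the median over probe sets of a gene, and leaving out probe sets that can match several transcripts (suffix _s_at or _x_at). Counts were also made at 1.5-fold and 3-fold and per probe set. After the data had been seen, 3 were added, namely only genes with 2 measured probe sets, both of these past 2-fold, and lists without genes at the floor.

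The size rule and the list percentiles were tested on simulated data made from 8477 genes of these arrays, with a noise SD of 0.64 and 200 altered genes. The rule picked up 55.2% of genes altered 2-fold, 89.6% of those altered 4-fold and 90.9% of those altered 8-fold, and 824 of 8277 unaltered genes (9.96%) also passed it. Of 100 lists of 20 genes with no shift, 5 lay outside the central 95%, and 99 of 100 lists shifted by 0.6 log2 units were picked up. The simulated knockout array was the control array with independent noise per probe set. It held no trend with signal, no 3' to 5' difference and no genes that move together. The simulation therefore checks the computing and does not show how often real lists lie outside by chance.

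Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Probe positions, transcript length and base composition were not analysed here.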

Results

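Uterine stromal cells are the connective tissue cells that lie under the uterine epithelium and decidualize, that is, enlarge and become secretory, around an implanting embryo. They were isolated from pregnant mice on day 5 by digesting the uterine horns with enzymes. RNA of cells pooled from 3 animals per genotype was measured on 2 Affymetrix Mouse Genome 430A 2.0 arrays, 1 from floxed controls and 1 from a conditional knockout. Each array gave a MAS5 signal for 22690 probe sets, with a trimmed mean signal of 150.1 on both arrays. The median signal was 41.8 on the control array and 34.4 on the knockout-labelled array, and 13828 and 13423 probe sets, respectively, lay above the floor of 19.7. There were no replicates, so no difference has a test, and each value describes these 2 arrays and not the genotypes. The number of arrays limits the precision, and the only error that could be estimated was the disagreement between 2 probe sets of the same gene, an SD of 0.64 on the log2 ratio scale (2660 genes). This SD leaves out the mean difference between the brightest and the next probe set. With that difference kept, the disagreement was a root mean square of 0.70.

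The comparison was between stromal cells of floxed controls and of mice labelled as lacking a gene in the uterus, through a Cre recombinase under the progesterone receptor promoter. The labels disagree on which gene that was, as the titles name Hif1, the genotype field names Hif2 alpha (encoded by Epas1), and the breeding note names Hif1 floxed mice and the ablation of Rac1. None of the 3 genes was depleted to the floor on the knockout-labelled array. Epas1 had a signal of 59.4 on the control array and 78.1 on the knockout-labelled array, a log2 ratio of 0.39. Hif1a had signals of 721 and 1544 at its brightest probe set, a log2 ratio of 1.10, and 2 further probe sets gave log2 ratios of 1.38 and 0.52. Rac1, a small GTPase of the cytoskeleton, had signals of 1038 and 757, a log2 ratio of -0.46, and its next probe set had signals of 664 and 332. The positions of these probes relative to the deleted exons were not analysed here, and a probe outside the deleted part does not check the genotype.

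Among 8593 genes above the floor on at least 1 array, 534 (6.21%) were at least 2-fold higher and 1119 (13.0%) at least 2-fold lower on the knockout-labelled array, and 6940 lay between. The highest ratios among genes measured on both arrays belonged to Bbip1, a subunit of the ciliary BBSome (signal 148 on the control array and 1045 on the knockout-labelled array, log2 ratio 2.82), Rpgrip1 (2.81), Tmed5 (2.60), Rif1, a regulator of replication timing (2.52), and Rpl27a, a ribosomal protein (5.66-fold). They were followed by Dio2, the deiodinase that activates thyroid hormone (2.47), Zfp52 (2.35), Sprr2f (2.31), Rev3l, the catalytic subunit of DNA polymerase zeta (2.23), and Rock1, a kinase of the actin cytoskeleton (2.23). Rock1 was higher at all 4 of its probe sets, with the other log2 ratios at 1.43, 1.49 and 1.67. The other probe set of Tmed5 gave 1.14. Further probe sets gave bounds of at least 0.99 for Rif1, 0.44 for Zfp52, and 0.57 and 0.20 for Dio2. All further probe sets of Rpgrip1, Rev3l and Rpl27a were at the floor on both arrays, so each of these genes rests on 1 probe set. Bbip1 and Sprr2f had only 1 probe set each.

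The lowest ratios belonged to Id1, an inhibitor of helix-loop-helix transcription factors and a target of BMP signalling (signal 454 on the control array and 47.2 on the knockout-labelled array, log2 ratio -3.27), Selenom (-3.26), Arf5 (-3.11), Apoe, a lipid carrier (-3.06), and Fcer1g, the signalling chain of Fc receptors (-2.93). Next came Fbln1, a matrix glycoprotein (-2.89), Mfap2, a protein of elastic microfibrils (-2.85), Banf1, a chromatin-binding protein (-2.80), A4galt (-2.76) and Cox8a, a subunit of cytochrome c oxidase (-2.76). Fbln1 was also lower at its other probe set (-3.20), as was Cox8a (-3.53), and Banf1 was lower at both of its others (-3.85 and -3.89). Id1, Selenom, Arf5, Apoe, Fcer1g, Mfap2 and A4galt had only 1 probe set each. Genes at the floor on 1 array give bounds only. Gsdme, Zfp991 and Zfp932 were at least 6.86-fold, 4.10-fold and 3.94-fold higher on the knockout-labelled array, and Pold4, Ubl5 and B3gnt9 were at least 6.50-fold, 5.55-fold and 5.09-fold lower. The other probe sets of Gsdme, Zfp991 and Ubl5 were at the floor on both arrays, and Zfp932, Pold4 and B3gnt9 had only 1 probe set each.

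The log2 ratios of the brightest and the next probe set had a Pearson r of 0.321 over 2660 genes, and 14 genes were past 2-fold in opposite directions. Among genes past 2-fold at the brightest, the next mostly gave the same sign and less often the same size. Of 283 genes whose brightest probe set was at least 2-fold higher, 208 were higher by any amount at the next one and 84 at least 2-fold, where 42.7% of all 2660 genes were higher at the next probe set. Of 137 genes at least 2-fold lower at the brightest, 108 were lower by any amount at the next and 56 at least 2-fold. The share of higher genes among those past 2-fold was 32.3% as deposited, and it was 46.4% after quantile normalization, 51.0% after median centring and 43.1% after removal of the trend with signal, so which direction prevailed depended on the scaling. Genes of high signal had higher ratios, from a median log2 ratio of -0.25 in the dimmest of 5 equal groups to 0.33 in the brightest.

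**Figure D1:**
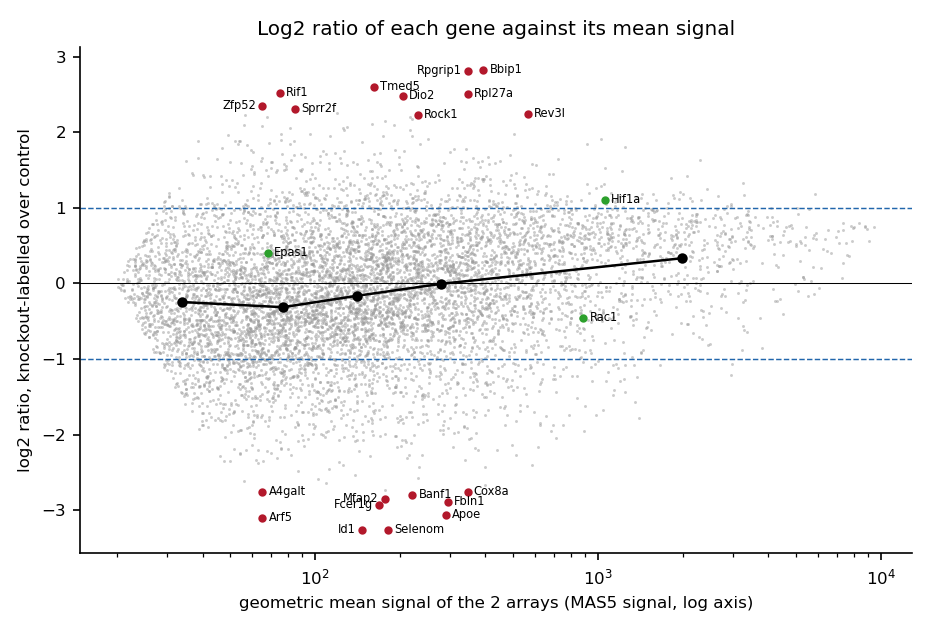
Log2 ratio of each gene above the floor on both arrays (knockout-labelled over control) against its geometric mean MAS5 signal on a log axis. Grey points are genes, red points the 10 highest and 10 lowest named genes, green points Epas1, Hif1a and Rac1, dashed lines 2-fold, and the black line joins the medians of 5 equal groups by signal, which run from -0.25 and -0.32 at low signal to 0.33 at high signal.

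The RNA measured on the 2 arrays also differed at its 5' ends. Signal of b-actin at the 3' end over the 5' end was 2.27 on the control array and 16.0 on the knockout-labelled array, and that of Gapdh was 1.49 and 7.25. For 18S rRNA, which has no poly-A tail, it was 0.449 and 1.29. The same ratio was higher on the knockout-labelled array for all 6 measured probe set pairs of the bacterial poly-A control transcripts dap, lys and phe, by factors of 1.53 to 4.03, of which those of lys and phe are lower bounds. It was not higher for the 7 measured pairs of hybridisation controls, with log2 differences of -0.30 to -0.03. This imbalance separates the arrays exactly as the genotype labels do, so it stands beside every gene group described here.

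**Figure D2:**
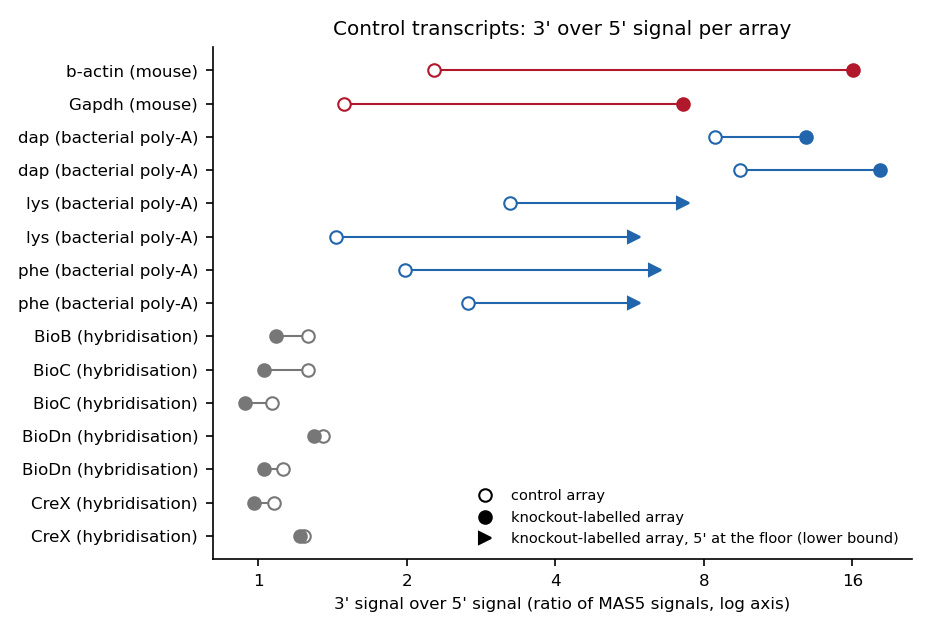
Signal at the 3' end over signal at the 5' end (ratio of MAS5 signals, log axis) of control transcripts on the control array (open circles) and the knockout-labelled array (filled circles, or triangles for a lower bound where the 5' end was at the floor). Mouse (red) and bacterial poly-A (blue) transcripts lie to the right on the knockout-labelled array, as b-actin at 16.0 against 2.27, and the hybridisation controls (grey) do not.

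The endothelial list and the smooth muscle and pericyte list both lay below genes of matched signal, although each held genes that were not lower. Of 22 endothelial markers compared, 9 were at least 2-fold lower and none at least 2-fold higher, with a median log2 ratio of -0.80, below that of all 10000 random lists matched on signal. Pecam1, an adhesion molecule of endothelial junctions, had a signal of 139 on the control array and 27.5 on the knockout-labelled array (log2 ratio -2.34), and Egfl7 (-1.79), Emcn (-1.58) and Ramp2 (-1.45) were also lower. Other endothelial genes, chosen after their values were seen, differed little, as the VEGF receptor Kdr (-0.33), the angiopoietin receptor Tek (-0.16) and Plvap (0.32). Flt1, Sox17 and Eng had log2 ratios of 0.07, 0.97 and 0.83 at their brightest probe sets, but Flt1 gave 0.80 and -0.43 or lower at others, and Sox17 and Eng gave -1.40 and -1.85, so their direction was not settled. Of 21 smooth muscle and pericyte markers, 6 were at least 2-fold lower and none at least 2-fold higher, with a median of -0.78 at percentile 0.01 of the matched random lists. Myl9, a myosin light chain, had signals of 1200 and 327 (log2 ratio -1.88), followed by Des (-1.67), Mcam (-1.66) and Hspb7 (-1.42), whereas Acta2 (0.56), also chosen after its value was seen, was higher. So chosen were the pericyte markers Rgs5 (0.57), Notch3 (0.17) and Abcc9 (0.11) and also Tpm2 (0.88), which were not lower at their brightest probe sets, although Rgs5 gave -0.42 and -0.76 at 2 others and Tpm2 gave -0.81 at 1, and Notch3 was at the floor on the knockout-labelled array at its next. Both lists lay outside the central 95% of random lists under all 9 other settings, on arrays that differed 7.08-fold in the b-actin 3' to 5' ratio. The random lists were not matched on the number of probe sets of a gene.

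Markers of myeloid cells were lower as a list and went both ways as genes. Of 26 compared, 9 were at least 2-fold lower and 2 at least 2-fold higher, with a median log2 ratio of -0.54 at percentile 0.11. By any amount, 14 were lower and 12 higher. Fcer1g and C1qa, a chain of complement C1q, were lower (log2 ratios -2.93 and -2.73), as were Cd68 (-1.95) and Aif1, at least 4.68-fold lower with the knockout-labelled array at the floor. Chosen after their values were seen, Ptprc, the pan-leukocyte antigen CD45, was higher (1.74) and C1qc was lower (-1.70). C1qb gave 1.58 at its brightest probe set and 0.54 and -2.68 at others, and H2-Aa gave 0.92 and -2.83, so their direction was not settled.

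The other marker lists lay within the central 95% of their random lists. Among 15 markers of uterine stroma, 1 was at least 2-fold lower, Hoxa11, a homeobox factor needed for decidualization (signals 389 and 107.7, log2 ratio -1.85), and the median of 0.06, at percentile 7.59, turned to -0.15 after quantile normalization and -0.07 after removal of the trend with signal. Among 27 markers of epithelium and glands, 4 were at least 2-fold lower and 2 at least 2-fold higher (median -0.39, percentile 3.48). The keratin Krt18 was lower (-2.20) and its filament partner Krt8, named in the embryo list, was higher (0.64). Cldn3 (-1.74) and Cldn10 (-1.71), both claudins of tight junctions, were lower and Ehf (1.37) was higher. Of 18 lymphocyte and NK cell markers, 4 were at least 2-fold lower and 1 at least 2-fold higher (median -0.45, percentile 13.8). The granzyme Gzmc (-2.06) and Il2rb (-1.27) were lower, Gzmd was at least 2.84-fold lower, and Klrd1 was higher (1.21). Of 6 granulocyte and mast cell markers, Cma1, a mast cell chymase, was at least 2.87-fold lower and Kit was lower (-1.17), with a median of -0.75 at percentile 8.49. The 4 embryo and trophoblast markers compared had none past 2-fold (median 0.22, percentile 77.3). The median turned to -0.37, at percentile 47.1, without _s_at and _x_at probe sets. Ttr was at 0.71, although 1 further probe set of Ttr gave a log2 ratio of -2.09 or lower. Too few mesothelium and erythrocyte markers were above the floor for a median, 2 of each, with Gpm6a at least 2.30-fold higher and Bpgm and Hbb-b2 at log2 ratios of 0.21 and 0.03. The next probe set of Bpgm went the other way, with a log2 ratio of -0.98 or lower.

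**Figure D3:**
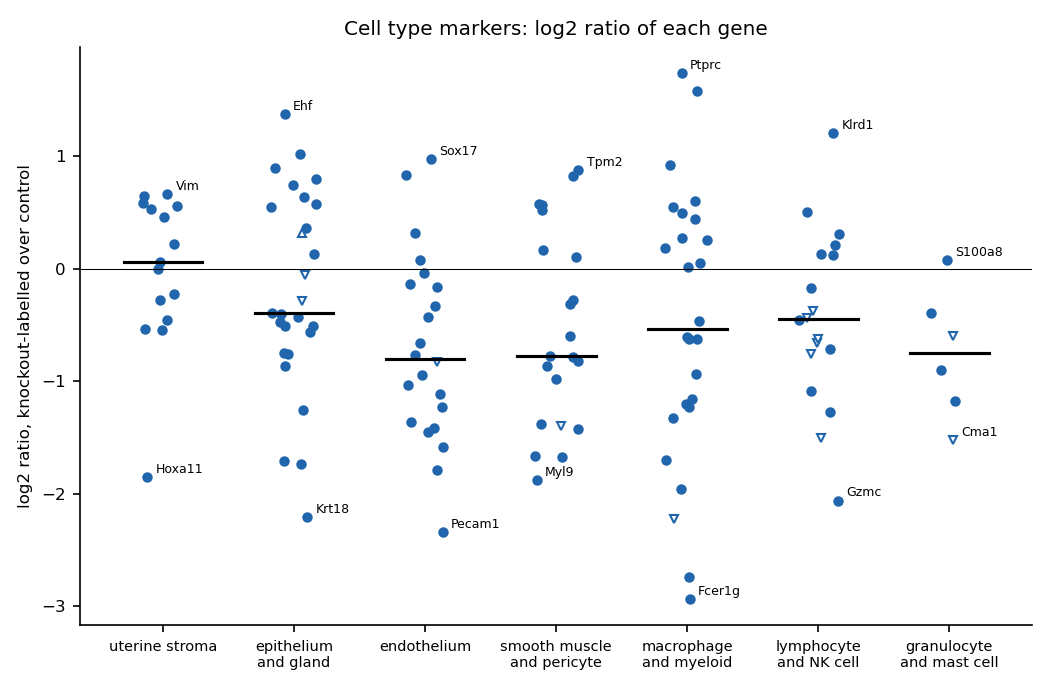
Log2 ratio (knockout-labelled over control) of each marker gene above the floor on at least 1 array, by cell type list. Filled points were measured on both arrays, open triangles are bounds that point to where the true ratio can lie, and bars are list medians, which lie at -0.80 for endothelium, -0.78 for smooth muscle and pericytes and -0.54 for myeloid cells, and at 0.06 for uterine stroma, where the sign depended on the scaling.

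Genes of decidualization and progesterone response lay lower than genes of the same signal. Of 34 compared, 3 were at least 2-fold lower and 2 at least 2-fold higher, with a median log2 ratio of -0.33 at percentile 0.34. Hoxa11 was lower (-1.85), as were Ccnd3, a D-type cyclin of decidual cells (-1.67), and Sfrp4, a secreted Wnt antagonist (signals 1573 and 512, log2 ratio -1.62). Ptgs2, the inducible prostaglandin synthase, had signals of 93.2 and 308 at its brightest probe set (1.72) but a log2 ratio of 0.23 at the other. The decidual prolactin genes Prl8a2 and Prl3c1 were at the floor on both arrays, as were Il11, Dkk1 and Cyp11a1. With the median over all probe sets of a gene in place of the brightest, the list lay at percentile 7, inside the central 95%.

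Extracellular matrix genes lay lower than genes of their signal. Of 41 compared, 7 were at least 2-fold lower and none at least 2-fold higher, and the median of -0.23 lay at percentile 0.03, where matched genes had a median of 0.28. Besides Fbln1 (-2.89), the lowest were Fbln2 (-1.88) and Timp1, an inhibitor of matrix metalloproteinases (-1.76), and Col12a1 was at least 2.42-fold lower. Of the 41, 17 were higher by any amount, among them, chosen after their values were seen, Col1a1 (0.59, with -1.26 at its other probe set), Col1a2 (0.54), Col3a1 (0.56), Dcn (0.65) and Vcan (0.80). Angiogenic factors lay inside the central 95% (23 compared, 3 at least 2-fold lower and 2 at least 2-fold higher, median -0.21, percentile 29.2). The median turned to 0.07, at percentile 74.1, with the floor at the 60th percentile, where 15 genes were compared. Adm, the vasodilator adrenomedullin (-1.62), and Pdgfb (-1.59) were lower, and Sema3a (1.62) and Pdgfa (1.19) were higher, although the other probe set of Pdgfa gave -0.25.

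The 3 lists of hypoxia-related genes lay inside the central 95% of their random lists. Of 8 components of the HIF pathway above the floor, Hif1a alone was past 2-fold (list median -0.07, percentile 60.3). Of 24 hypoxia-responsive genes outside glycolysis, 5 were at least 2-fold lower and none at least 2-fold higher (median -0.06, percentile 56.2), and both medians turned positive after quantile normalization. The collagen-modifying enzymes Plod1 (signals 249.8 and 59.3, log2 ratio -2.07) and P4ha2 (-1.24) were lower, with Adm and Pdgfb. Vegfa, chosen after its value was seen, had signals of 157 and 198 (0.34), with -0.04 at its other probe set. Of 17 genes of glycolysis and lactate, 2 were at least 2-fold lower, the glycolytic enzymes Pkm (-1.28) and Pfkm (-1.25), and 1 was at least 2-fold higher, the glucose transporter Slc2a1 (1.07), whose dimmest probe set gave -0.69 (list median -0.38, percentile 6.99). That median lay -0.37 from matched genes, where the decidualization list lay -0.36 from them. Without _s_at and _x_at probe sets the 2 lists parted, at -0.06 (percentile 39.4) for glycolysis and -0.30 (percentile 1.52) for decidualization.

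Vesicle trafficking genes, 36 in number, had 6 at least 2-fold lower and 1 at least 2-fold higher (median -0.10, percentile 13.5, turning to 0.03 after median centring). Vamp8, a fusion protein of secretory vesicles (-1.81), the tetraspanins Cd82 (-1.47) and Cd9 (-1.27) and the early endosome GTPase Rab5c (-1.45) were lower, and the secretory GTPases Rab27a and Rab27b were at the floor on both arrays. Genes of the unfolded protein response and autophagy lay lower as a list (27 compared, 6 at least 2-fold lower and 1 at least 2-fold higher, median -0.31, percentile 0.85), but at percentile 4.50 after quantile normalization and 6.78 after removal of the trend with signal. Its lowest members were the autophagy genes Gabarap (signals 1128 and 234, log2 ratio -2.27), the cargo receptor Sqstm1 (-1.99) and Map1lc3a (-1.86). The list pools both processes, so autophagy genes alone were not ranked as a fixed list. Genes whose symbols start with Atg, 13 in number and grouped after the data were seen, lay at percentile 34.9 (median -0.39). Atf4, a transcription factor of the stress response, gave 1.32 at its brightest probe set and -0.87 at the next, so its direction was not settled.

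The lists of inflammatory and interferon genes lay inside the central 95% of their random lists. Of 28 prostaglandin, chemokine and inflammatory genes, 5 were at least 2-fold lower and 4 at least 2-fold higher (median -0.28, percentile 9.71), with the monocyte chemokines Ccl7 (-2.62), Ccl2 (-1.96) and Ccl3 (-1.89) lower. The 4 higher were Ptgs2 (1.72) and Socs3 (1.17), both with a further probe set that did not reach 2-fold, and, chosen after their values were seen, Ptger2 (1.22) and Il6 (1.11). Of 25 interferon response genes, 5 were at least 2-fold lower and none at least 2-fold higher (median -0.36, percentile 12.9), among them the immunoproteasome subunits Psmb9 (-2.58) and Psmb8 (-1.43), the tetherin gene Bst2 (-2.09) and Oasl2 (-1.77). Of 25 genes of the dissociation and immediate-early response, 5 were at least 2-fold lower and 1 at least 2-fold higher, and the median of 0.07, at percentile 8.40, turned to -0.17 after quantile normalization and -0.24 after removal of the trend with signal. Under these settings the list lay outside the central 95%, at percentiles 2.11 and 1.61. Zfp36 (-1.30), Klf2 (-1.27) and Junb (-1.24) were lower. Socs3, a suppressor of cytokine signalling, gave 1.17 at its brightest probe set and -0.12 at its probe set without the suffix that marks possible cross-matching, so its direction was not settled.

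Cell cycle genes went both ways, with 7 of 36 at least 2-fold lower and 4 at least 2-fold higher (median -0.04, percentile 59.7, turning to 0.04 after quantile normalization). The mitotic kinase Plk1 (-1.89), the replication helicase subunit Mcm5 (-1.77) and Ube2c (-1.73) were lower. Hmmr gave 1.60 at its brightest probe set and 0.06 and -0.11 at the next ones, and Mki67, the proliferation antigen, chosen after its value was seen, was higher (1.54). Oxidative phosphorylation genes had 8 of 37 at least 2-fold lower and 1 at least 2-fold higher, and the median of 0.27, at percentile 29.4, turned to -0.08 after removal of the trend with signal. Cox8a (-2.76), Atp5g1 (-1.97), Ndufs4 (-1.85, with 0.72 at its next probe set) and Sdhc (-1.80) were lower. Of 23 ribosomal protein genes, 2 were at least 2-fold higher, Rpl27a (5.66-fold) and Rps25 (1.06), and 2 at least 2-fold lower, Rps19 (signals 4492 and 1943, log2 ratio -1.21) and Rpl11 (-1.06). The median of 0.12, at percentile 2.78, turned to -0.28 after quantile normalization and -0.24 after removal of the trend with signal. Under these settings the list lay outside the central 95%, at percentiles 0.125 and 0.760. It lay well inside with the median over probe sets, at percentile 49.5, and inside without _s_at and _x_at probe sets, at percentile 11.2.

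**Figure D4:**
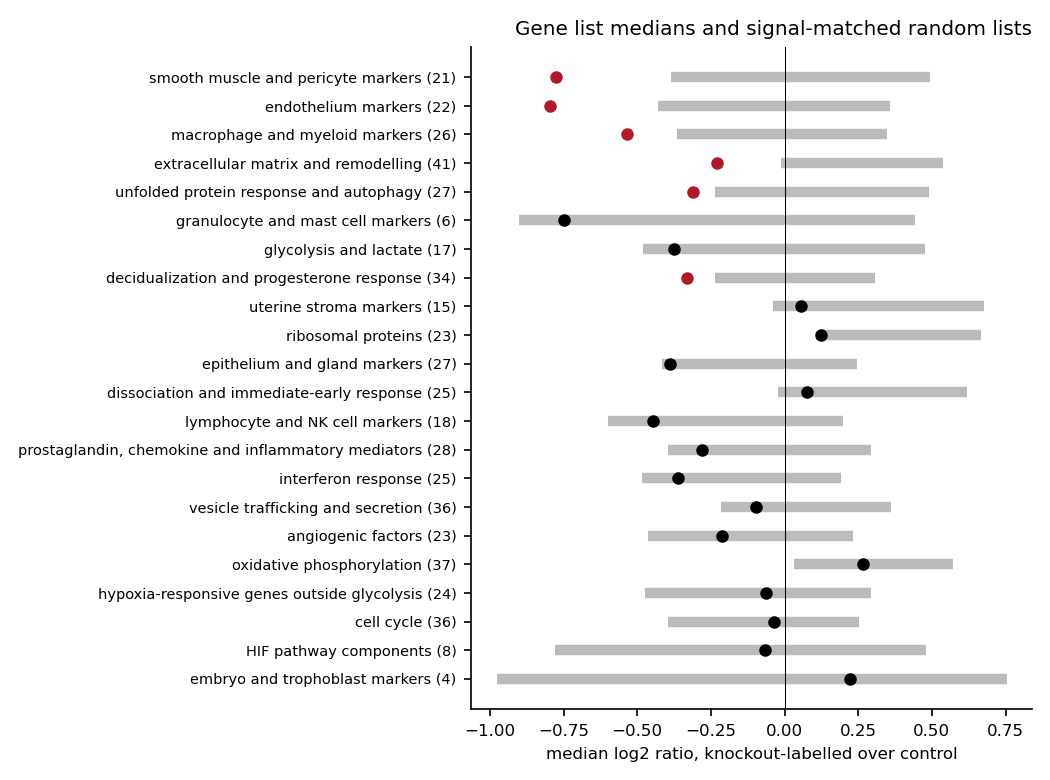
Median log2 ratio (knockout-labelled over control) of 22 gene lists, with the number of genes compared in brackets. Points are list medians, red where they lie outside the grey bar, which spans the central 95% of medians of 10000 random lists matched on signal, and the 6 red points all lie below it.

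Of the 22 lists with a median, 6 lay below the central 95% of their random lists and 0 above. Independent genes in separate lists would put 1.1 outside. Some lists share genes, and genes of a list can move together, so the excess over 1.1 does not exclude chance. The random lists were also not matched on the number of probe sets of a gene. Genes with 2 measured probe sets were 283 higher and 137 lower, against 534 and 1119 over all genes. With the median over probe sets, endothelium, smooth muscle and myeloid lists lay at percentiles 0.03, 0.57 and 0.03. Median centring moved the median log2 ratio of all genes by 0.16, so lists are set against genes of matched signal and not against 0.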

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

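The tests of degraded RNA, of hybridisation and of the labelling reaction were chosen only after the result was seen, and those of a trend with signal were set out before.

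Control probe sets, which enter no gene comparison, carried a pair of signals that separate the arrays. The median 3' to 5' ratio of the bacterial poly-A transcripts was higher by a factor of at least 2.64 on the knockout-labelled array. Hybridisation controls, which by textbook practice are added after labelling, had signals on the knockout-labelled array that were 1.96-fold those on the control array in the median of 14 probe sets, with a range of 1.76-fold to 2.88-fold.

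The first pattern is the higher 3' to 5' ratio of control transcripts on the knockout-labelled array. Degraded cell RNA as the whole cause is argued against by the bacterial poly-A transcripts, which no mouse cell made and whose smallest mean log2 difference was 0.78, and uneven hybridisation or scanning by the hybridisation controls, whose median difference was -0.14. Less full-length product in the labelling reaction remains a candidate explanation, since the mouse messenger and bacterial transcripts were all higher, with a median difference of at least 1.59, a bound because the 5' ends of lys and phe were at the floor. That reading rests on the usual practice of adding the bacterial transcripts before labelling, which the labels do not state, and degraded RNA may still add to the mouse differences of 2.82 for b-actin, 2.28 for Gapdh and 1.52 for 18S rRNA, which has no poly-A tail and was left out of that median. Of the bacterial transcripts, dap alone had both ends above the floor on both arrays. Its log2 differences, 0.62 and 0.94, were smaller than those of b-actin and Gapdh. The genotype and the labelling reaction are the same split of the arrays, so gene differences from either were not separated here.

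The second pattern is the lower median of the endothelial, smooth muscle and myeloid marker lists on the knockout-labelled array. Of 26 myeloid markers, 12 were higher by any amount. From genes of matched signal the list medians lay -0.75 for endothelium, -0.84 for smooth muscle and pericytes and -0.53 for myeloid cells. That argues against a trend of ratio with signal as the whole cause. After the loess trend was removed, the medians themselves were -0.75, -0.61 and -0.35, in the same order. The median of all genes was then -0.01, and 3 of the 3 lists still lay outside the central 95% of random lists. The 3 lists already lay below genes of matched signal, so neither these medians nor these percentiles are a separate test of a trend. The myeloid log2 ratios had an SD of 1.23 (interval 0.90 to 1.47). Without Ptprc, C1qb and H2-Aa, left out after their values were seen, it was 1.07 (0.77 to 1.28). Both intervals lie above the probe set disagreement, a root mean square of 0.70. That disagreement leaves out the spread between labelling reactions, and the SD over all genes, 0.78, lies inside the second interval. The myeloid spread therefore cannot decide whether an even loss of myeloid cells was the whole cause. For endothelium (0.59 to 1.03) and smooth muscle (0.67 to 1.01) the intervals hold 0.70 and cannot decide it either. Fewer cells of these types in the digest, lower expression per cell, the labelling difference and the genotype were not separated here.

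The third pattern is that the brightest probe set of a gene gave a higher log2 ratio than the next one, by 0.41 on average (0.37 to 0.44) over 2660 genes. A trend with signal as the whole cause is argued against, because 0.30 (0.26 to 0.33) of the difference was left after the loess trend was removed. A different distance of probe sets from the 3' end is a candidate explanation beside it that was not tested, as probe positions were not analysed here.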

How the results depend on the processing

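The settings with only genes of 2 probe sets, with both probe sets past 2-fold and without genes at the floor were chosen after seeing the data. Genes at least 2-fold higher numbered 534 as reported and 857 after median centring, and genes at least 2-fold lower numbered 1119 and 601 with the floor at the 60th percentile, where fewer genes were compared. Other thresholds gave 1592 higher and 2268 lower at 1.5-fold, and 106 and 330 at 3-fold. Counted per probe set they were 996 and 2010. Over the 2660 genes with 2 measured probe sets there were 283 higher and 137 lower, opposite in balance to all genes, and 84 and 56 with both probe sets past 2-fold. The other planned settings gave 364 to 709 higher and 819 to 1336 lower genes, within 1.5 times the reported counts. The 32.3% share of higher genes was 24.9% with the median over probe sets. Of 789 values of 100 named genes under the planned settings, 745 moved by less than the probe set disagreement, 42 moved by more and 2 reversed, Atf4 to -0.87 and Socs3 to -0.12, both without _s_at and _x_at probe sets, where another probe set stands for the gene. Of 94 named genes past 2-fold, 88 stayed past it after removal of the loess trend, 84 with the median over probe sets, and 74 of the 88 that kept a value with the floor at the 60th percentile. The difference of ribosomal protein genes from matched genes went from -0.34 to -0.00065 with the median over probe sets, and that of lymphocyte and NK cell markers from -0.23 to 0.18 without genes at the floor; the cause was not tested. Endothelium, smooth muscle, myeloid and matrix lists stayed below the central 95% of random lists under all 9 settings, decidualization under 8 and the unfolded protein response and autophagy list under 6. Ribosomal proteins lay outside it under 4 settings, the immediate-early list under 2, and vesicle trafficking and lymphocyte markers under 1 each. Granulocyte markers gave no value with the floor at the 60th percentile. No paired analysis was possible because each group has 1 array, and none could be left out for the same reason. Signal over background limits the 3800 genes at the floor, which have no ratio.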

Other observations

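All comparisons in this part were chosen after the data had been seen, as were the gene families and the genes named from them.

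Genes grouped by the stem of their symbol showed families that stood apart on the knockout-labelled array. Of 64 stems with at least 12 genes, 6 lay below the central 95% of random lists matched on signal and 5 above. Independent genes would put 3.2 outside, and genes of a family need not be independent. Genes of mitochondrial ribosomal proteins lay below genes of the same signal as families, although 16 of 47 Mrpl genes and 5 of 27 Mrps genes were higher by any amount. Of 47 Mrpl genes of the large subunit, 14 were at least 2-fold lower and 2 at least 2-fold higher (median log2 ratio -0.49, percentile 0.14), and of 27 Mrps genes of the small subunit, 8 were lower and 0 higher (-0.64, percentile 0.11). Mrpl27 had a signal of 469 on the control array and 94.4 on the knockout-labelled array (log2 ratio -2.31), and Mrps16 had 412 and 91.9 (-2.17). Of 13 Timm genes of the mitochondrial inner membrane import machinery, 5 were at least 2-fold lower and 0 higher (-0.87, percentile 0.10), among them Timm13 (-1.95). Also below were 26 Med genes of the Mediator complex (-0.60, percentile 0.89), 14 Psmd genes of the proteasome regulatory particle (-0.46, percentile 2.34) and 12 Ndufa genes (-0.22, percentile 1.02). Relative to matched genes, these medians stayed negative after removal of the loess trend, as for Mrpl at -0.34, Mrps at -0.56 and Timm at -0.82.

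Zfp genes, which encode zinc finger proteins, lay above genes of the same signal as a family, with 79 of 118 higher by any amount. Of 118 Zfp genes, 25 were at least 2-fold higher and 5 at least 2-fold lower, with a median log2 ratio of 0.38, above all 10000 random lists, and a difference from matched genes of 0.58, or 0.51 after removal of the loess trend. Zfp948 had a signal of 25.1 on the control array and 97.3 on the knockout-labelled array (log2 ratio 1.96), Zfp955a had 53.3 and 151 (1.51) and Zfp148 had 87.1 and 215 (1.31). Also above were 12 Ankrd genes (0.66, percentile 99.8), 13 Cep genes of the centrosome (0.38, percentile 99.3), 17 Kif genes of kinesin motors (0.27, percentile 98.1) and 44 Rnf genes (0.19, percentile 97.8). Whether transcript length or base composition, which differ between such families, goes with these shifts was not analysed here.

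The log2 ratios of 37 oxidative phosphorylation genes, which pool subunits of 5 complexes, had an SD of 0.98 (bootstrap interval 0.75 to 1.17), and those of 23 ribosomal protein genes an SD of 0.77 (0.45 to 1.05). Random lists matched on signal had a median SD of 0.67 and 0.57, respectively, which put the lists at percentiles 99.9 and 95.9, and probe set disagreement gives a root mean square of 0.70.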
